A study of Mus musculus with 2 samples.

How the data were processed

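Single-cell RNA expression was measured in pancreatic cells of R26[CA]30EYFP mice on a C57Bl/6J background after pancreatitis. Cells sorted as EYFP positive and as EYFP negative made 1 library each. Per the labels' protocols, the libraries were made with the Chromium Single Cell 5′ kit, version 1.1, and each was sequenced on its own lane. The kit is given as labelled, but the barcode sequences left it in doubt whether this 5′ kit or a 3′ kit was used. No list of kit barcodes was used here to settle this, so the transcript end that was read is not taken as known. The number of animals per library and the time after pancreatitis are not given in the sources used here. The deposited values are whole-number UMI counts per gene and barcode, and the authors deposited them without normalization as far as the values show. Per the submitters' processing notes the counts came from Cell Ranger 2.1.0 and the build was GRCh38. Per the file headers the software version was 3.1.0, and the gene identifiers are mouse Ensembl identifiers. These sources differ, so the mapping build is not taken as known, and the coordinates given are those of GENCODE M21 for the same gene identifier. The feature table of 31053 genes holds no reporter transcript, so the sort was not checked from the counts.

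Barcodes with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which left 860 of 1717 EYFP positive and 553 of 745 EYFP negative barcodes. Both libraries were clustered together with scanpy 1.11.5 in Python 3.11.15, from genes found in at least 3 cells, with counts scaled to 10000 per cell, log1p values, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0. No batch correction was made, since library and group are the same. Doublets were kept. Scrublet marked 2 EYFP positive and 5 EYFP negative cells, and their removal was an alternative.

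The marker genes of each cell type, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined, and the closing section names the alternatives chosen later. The scoring rule that turns markers into cluster names was not. It was written after the clusters were seen, and 4 versions were tried with their output in view. The first compared a cluster's summed CPM with all other cells. The next compared it with the median cluster of the same library, the next used the geometric mean over cells, and the last, used here, also left a cluster unnamed where its 10 leading genes held as many markers of another type. A name needed at least 3 markers at 2-fold or more with at least 5 UMIs, and a low-UMI cluster without an own marker among its leading genes stayed unnamed. The earlier versions are among the alternatives, and the class shares under them are given in the closing section. A class is called X-like because it rests on markers alone.

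With 1 library per group there is no replicate and no test. UMIs were summed per library and class and divided by the sum's total (CPM). Folds are EYFP positive over EYFP negative unless said otherwise. They carry an exact conditional binomial 95% interval for a ratio of Poisson counts, shares carry an exact Clopper-Pearson 95% interval, and both cover counting error only. A share of 0 is given with the limit of 3 counts of the total instead. No p-value was made from cells. A fold against 0 UMIs was taken against a floor of 3 UMIs in the sum and is a lower bound. No fold is given where both libraries held at most 3 UMIs. Gene folds under the alternatives follow the same rules, with no pseudocount. A gene list is described by the median log2 fold of its members with at least 10 UMIs, with a pseudocount of 0.5 UMI, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a p-value.

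Named genes followed a fixed rule. Ogn was always named. For the whole libraries and each class with at least 20 cells in both, genes with at least 30 UMIs were ranked by the interval bound nearest to 1, leaving out mitochondrial, ribosomal, predicted and sex-linked genes and the acinar secretory list. The top 12 each way were taken for the whole libraries and the top 10 each way per class. Up to 4 members with the most UMIs were taken from each list. Some genes that the rule takes are not reported here. Some lists overlap with each other or with the naming markers. The iCAF list holds Ogn, which the series' title names, and the fibroblast markers Pdgfra, Dpt and Col14a1. The proteoglycan list holds Ogn and the markers Dcn and Lum. Reg1, Spink1 and Gp2 stand in both the pancreatitis and the acinar secretory list. The pancreatitis list also holds the ductal markers Clu, Onecut2, Krt19, Sox9, Spp1, Tff2 and Mmp7. The collagen list holds the fibroblast markers Col1a1, Col1a2, Col3a1, Col6a1 and Col6a2. Il6, Il33, Ccl2, Ccl7, Cxcl1, Cxcl2 and Cxcl12 stand in both the cytokine and the iCAF list. Whole-library medians of these lists are thus not independent of the class names. For each named gene the share of its UMIs held by 1 cell was computed, an alternative added after seeing the data. To compare shares of cells with an Ogn UMI, cells were thinned to 500 or 1000 UMIs.

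The fold and list steps were tested on simulated counts. These were independent Poisson draws around the library sums, without variation between cells, library effects or correlation between genes. The rates below therefore check the calculation only. They do not hold for genes set by single cells or for lists whose members vary together. In the simulated comparison of whole libraries (11040 genes), 89 of 100 genes changed 2-fold and 100 of 100 changed 4-fold had an interval on the right side of 1. In the T-like simulation (7950 genes) these were 71 and 98, and in the B-like simulation (3960 genes) 65 and 100. Of 100 lists of unchanged genes, 98, 95 and 91 lay in the central 95% of matched random lists in these simulations.

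Alternatives changed the barcode filter, the clustering resolution, the clustering of both libraries together, the genes used in clustering, the doublets, the scaling, the thinning and the count minimum. Depth differed widely: the median kept cell held 1007.5 UMIs in the EYFP positive and 8020 in the EYFP negative library, so a gene at a few UMIs per cell is seen less often in the former.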

Results

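The mice carried a Rosa26 EYFP reporter with a CA repeat of 30 units, a design in which EYFP is read only after a change in the length of the repeat. Pancreatic cells taken after pancreatitis were sorted into EYFP positive and EYFP negative cells, and each fraction was profiled as 1 single-cell library. The comparison asks which cells each fraction held and how their transcripts differed. The series names osteoglycin (Ogn), a small leucine-rich proteoglycan of the extracellular matrix, in connection with inflammatory cancer-associated fibroblasts (iCAF). The EYFP positive library held 1717 barcodes and 4006807 UMIs, and the EYFP negative library 745 barcodes and 5295816 UMIs. After filtering, 860 cells with 2745342 UMIs and 553 cells with 4857210 UMIs remained, with a median of 427 and 2269 genes per cell. Of the kept cells, 49.7% held under 1000 UMIs in the EYFP positive library and 0.904% in the EYFP negative library. Each group is 1 library, so no difference below has a replicate check, and intervals cover counting error only.

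The EYFP negative library was mostly lymphocytes, and the EYFP positive library was a mixture of epithelial, stromal and lymphoid cells. T-like cells made up 26.5% (23.6 to 29.6) of EYFP positive and 70.3% (66.3 to 74.1) of EYFP negative cells, and B-like cells 12.8% (10.6 to 15.2) and 19.2% (16.0 to 22.7). Ductal or metaplastic epithelial-like cells, led by Spp1, Clu, Krt8 and Krt18, made up 26.2% (23.3 to 29.2) and 0.362% (0.0438 to 1.30). Acinar-like cells made up 10.5% (8.50 to 12.7) and 0.181% (0.00458 to 1.00), fibroblast-like cells 7.44% (5.78 to 9.40) and 1.08% (0.399 to 2.35), and blood endothelial-like cells 6.74% (5.16 to 8.63) and 1.99% (0.997 to 3.53). Macrophage or monocyte-like cells stood at 3.14% (2.08 to 4.54) and 1.99% (0.997 to 3.53), intervals that overlap, but this depends on the setting. The shares were 6.16% and 1.99% with names from summed CPM against all other cells, and 1.98% and 1.81% at resolution 2.0. With at least 500 genes and at most 10% mitochondrial UMIs per barcode they were 7.06% and 1.87%. NK or innate lymphoid-like cells were 14 of 553 in the EYFP negative library and 0 of 860 in the other. That 0 rests on the naming rule. A cluster of 31 EYFP positive cells with Nkg7, Xcl1 and Gzma but also Clu and Spp1 among its leading genes stayed unnamed. No upper limit and no deficit of such cells in the EYFP positive library is therefore read from the 0. Another 26 EYFP positive cells, led by hemoglobin and macrophage genes, stayed unnamed too, so that unnamed cells made up 6.63% (5.06 to 8.50) of the EYFP positive library and 0 of 553 in the other, which allows up to 0.542%. Erythroid-like cells numbered 1 and 13.

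**Figure D1:**
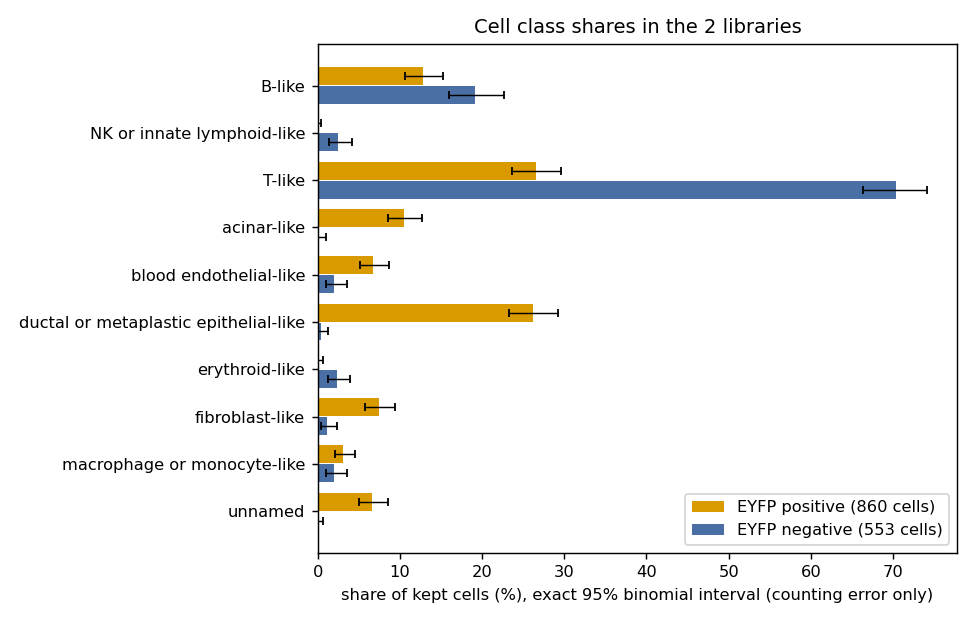
Share of kept cells per class in percent, for the EYFP positive (860 cells) and EYFP negative (553 cells) library. Bars are shares and whiskers exact 95% binomial intervals. T-like cells reach 70.3% of the EYFP negative library, and ductal-like cells reach 26.2% of the EYFP positive library under the naming rule used.

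These shares depend on how clusters are named. Most ductal-like cells came from 1 cluster of 197 EYFP positive cells with a median of 762 UMIs. Under either naming rule based on summed CPM this cluster was not ductal-like, and the ductal-like share was 3.26% against 0.362%. Under the rule that compares summed CPM with all other cells, the low-UMI T-like cluster of 144 EYFP positive cells lost its name too. Other T-like cells lost it as well: 22 EYFP positive and 356 EYFP negative cells stayed T-like, against 228 and 389 under the rule used. The T-like share was then 2.56% against 64.4%, and the acinar-like share 27.2% against 0.181%. The blood endothelial-like share was 2.67% against 1.63% under both of these rules. With a class given to each cell from its marker UMIs, acinar-like cells made up 60.7% against 0.542%, fibroblast-like cells 3.49% against 1.27% and ductal-like cells 8.49% against 0.362%. With each library clustered by itself, 25 EYFP negative cells were fibroblast-like, and the rule named 194 EYFP positive and 0 EYFP negative cells T-like. No cluster was macrophage or monocyte-like at resolution 0.5. Acinar secretory genes took 4.38% of kept UMIs in the EYFP positive library and 0.107% in the other. Lars2 and Gm42418, whose counts can include ribosomal RNA fragments, took 8.28% and 0.343%.

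Ogn (ENSMUSG00000021390, chromosome 13, 49608046 to 49624501, plus strand in GENCODE M21) was found in fibroblast-like cells of both libraries, and at a higher level in the EYFP positive cells. The 64 EYFP positive fibroblast-like cells held 327 Ogn UMIs, or 1971 CPM (1763 to 2196), and the 6 EYFP negative ones held 22, or 464 CPM (291 to 703), a fold of 4.24 (2.75 to 6.86). Outside fibroblast-like cells, the EYFP positive library held 0 Ogn UMIs in 796 cells, which allows up to 1.16 CPM, and the EYFP negative library held 1 UMI in 547 cells, in a macrophage or monocyte-like cell. A UMI was seen in 44 of 64 cells (68.8%, 55.9 to 79.8) at a median of 707 UMIs and in 3 of 6 (exact interval 11.8% to 88.2%) at a median of 8838 UMIs. No T-like cell of either library had one, at medians of 1209 and 8543 UMIs. Thinned to 500 UMIs, 33 of 64 EYFP positive cells (51.6%, 38.7 to 64.2) and 0 of 6 EYFP negative cells had one. The level was then 1406 CPM (1026 to 1882) in the former and 0 CPM (exact interval up to 1230) in the latter. Thinned to 1000 UMIs it was 1130 CPM (738 to 1656) and 200 CPM (5.06 to 1114). At equal depth the intervals thus overlapped. The thinned EYFP negative sums of 3000 and 5000 UMIs held 0 and 1 Ogn UMIs, so wide intervals were nearly fixed. The overlap therefore says little on the fold. Among cells with at least 5000 UMIs, a limit chosen after seeing the data, Ogn stood at 2318 CPM (2049 to 2612) in 10 EYFP positive cells and 473 CPM (296 to 716) in 5 EYFP negative cells. Those 10 cells held 269 of the 327 EYFP positive Ogn UMIs, so the fold rests mainly on them. The cell with the most Ogn UMIs held 72 of the 327 EYFP positive and 11 of the 22 EYFP negative UMIs.

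**Figure D2:**
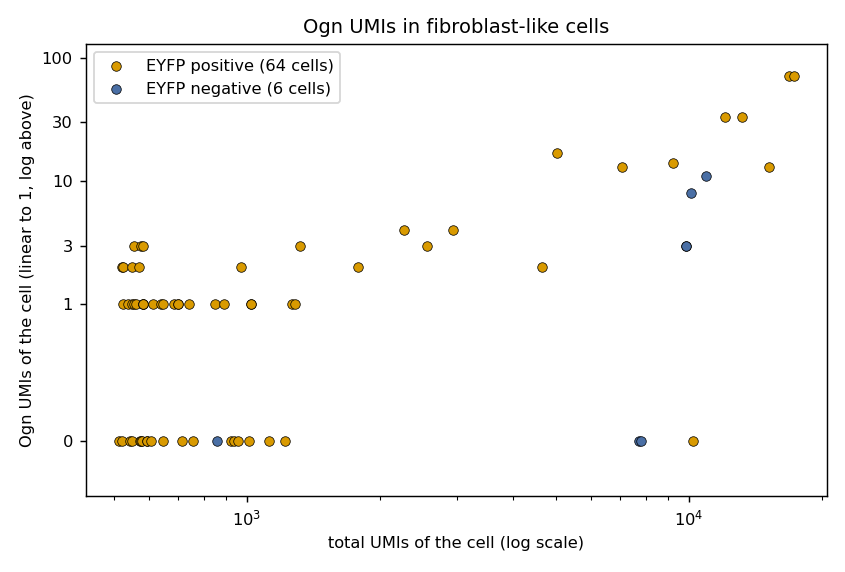
Ogn UMIs of each fibroblast-like cell against the cell's total UMIs, on a log axis, with the vertical axis linear to 1 and logarithmic above. Each point is a cell, 64 from the EYFP positive and 6 from the EYFP negative library, and the highest EYFP positive cell holds 72 Ogn UMIs against 11 in the highest EYFP negative cell.

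Among fibroblast-like cells, most immediate early genes were lower in the EYFP positive library, while members of the iCAF list and of the list of the myofibroblastic state (myCAF) went both ways. Only 6 EYFP negative cells stand behind every one of these folds. Of 10 measured iCAF genes 6 were higher and 4 lower, with a median log2 fold of 1.05 (percentile 99.95) and an interval over members of -0.42 to 2.21. With members from 1 UMI instead of 10, the median was 0.15. The list includes Ogn, Clec3b (fold 2.05, 1.57 to 2.72), Dpt (2.12, 1.60 to 2.84) and the complement gene C3 (0.860, 0.673 to 1.11). Of 9 myCAF genes 3 were higher and 6 lower (median -1.37, -2.17 to 0.92 over members, percentile 0.14), and of 8 small leucine-rich proteoglycans 2 were higher and 6 lower (median -1.04, -1.40 to 1.25, percentile 1.12). Ogn went against the other abundant proteoglycans: Dcn stood at 0.506 (0.470 to 0.545), Lum at 0.508 (0.406 to 0.639) and Bgn at 0.216 (0.147 to 0.317). Of 16 immediate early and stress genes 13 were lower, with a median log2 fold of -1.18 (-1.69 to -0.75 over members, percentile 0.01), among them Fos (0.485, 0.378 to 0.625), Jun (0.441, 0.362 to 0.537) and Egr1 (0.443, 0.352 to 0.561). Of 6 measured cytokines and chemokines 5 were lower, with a median of -1.40 (-2.07 to 1.07 over members, percentile 0.44), such as Cxcl12 (0.264, 0.164 to 0.424), whereas the alarmin Il33 was higher (7.71, 2.55 to 38.1). Of 15 collagen and basement-membrane genes 13 were lower and 2 higher, with a median log2 over all 15 of -0.41, at percentile 6.96. Matrix remodelling genes had a median of 0.23 (percentile 93.1), with Timp2 at 4.29 (2.96 to 6.45), and unfolded protein response and interferon genes had medians of -0.30 (percentile 46.5) and 0.59 (percentile 91.8). All 22 measured acinar secretory genes were higher here too, with a median of 5.23, or 2.71 with genes at 0 UMIs set at their bound, as were the 3 measured pancreatitis genes (3.55, or 0.93 at their bound, and 1.65 with members from 1 UMI).

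Over all kept cells, where composition and expression are mixed, fibroblast and acinar transcripts were higher in the EYFP positive library and erythroid and mitotic transcripts lower. The median log2 fold of all genes was 0.14, and -0.07 when acinar, mitochondrial and ribosomal genes were left out of the total. Rbpjl, an acinar transcription factor, was at least 335-fold higher (568 UMIs against 0). Serpini2 was 451-fold higher with 1 UMI in the other library (80.3 to 17889), Nupr1, a stress-induced regulator, 87.1-fold (64.4 to 121) and Col7a1 at least 57.2-fold. Pi16, which is also a marker used to name fibroblasts, was 384-fold higher (106 to 3180) and Fn1 140-fold (63.7 to 383), with log2 folds of 6.32 and 6.15 as means over cells. All 12 measured iCAF genes were higher, with a median log2 of 3.63 (percentile 100), as were 15 of 15 collagen genes (2.43, percentile 100), 13 of 13 matrix remodelling genes (2.75, percentile 99.94) and 8 of 8 small leucine-rich proteoglycans (1.69, percentile 99.01). Ogn itself was 25.2-fold higher (16.5 to 40.2). Of 14 myCAF genes 12 were higher (median 2.47, or 2.37 with genes at 0 UMIs at their bound, percentile 100), while Thy1 (0.391, 0.339 to 0.448), which T cells also express, and Tgfb1 (0.543, 0.451 to 0.651) were lower. All 11 measured pancreatitis genes were higher (median 4.88, or 4.53 with genes at 0 UMIs set at their bound, percentile 100), including Reg1 (53.1, 44.1 to 64.5), Spp1 (15.4, 14.6 to 16.2) and Clu (12.2, 11.3 to 13.1). Spp1 and Clu are also markers used to name ductal-like cells. All 35 measured acinar secretory genes were higher, with a median of 5.41. Of 14 cytokines and chemokines 11 were higher (median 1.73, percentile 99.75). Immediate early genes had a median of 0.27 (percentile 97.59), with Jun at 2.74 (2.61 to 2.89) and Junb at 0.825 (0.773 to 0.879). The MHC class II, unfolded protein response and interferon lists had medians of -0.22, 0.39 and 0.28, at percentiles 27.2, 96.0 and 74.8.

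Several of the most extreme whole-library folds came from 1 cell. Ppy, the pancreatic polypeptide hormone, had 21581 UMIs against 1, a fold of 38182 (6852 to 1508190), but 21498 of them lay in 1 EYFP positive cell with 53707 UMIs. The same cell held 7729 of 7766 UMIs of Pyy, 120 of 121 of Pcsk2, 119 of 120 of Resp18 and all 95 of Scg2, genes of endocrine secretory cells, and without it Ppy stood at 83 UMIs against 1. By its cluster of 197 EYFP positive cells it was nevertheless classed as ductal-like. Of 114 UMIs of Myh11, a smooth muscle myosin, 113 lay in another cell, which was classed as blood endothelial-like. In the EYFP negative library, 6821 of 7016 Ighg2b UMIs lay in 1 B-like cell, against 3 UMIs in the EYFP positive library. That cell held 89 of 92 UMIs of Igkv1-122, and another held 200 of 202 of Ighv3-6 and 184 of 188 of Igkv12-46. Without it the last 2 genes stood at 1 UMI against 2 and 2 UMIs against 4. The hemoglobin genes Hbb-bt and Hba-a1 were 17.0-fold (15.1 to 19.1) and 15.2-fold (14.1 to 16.4) lower in the EYFP positive library, with log2 folds of -2.22 and -1.54 as means over cells. Slc4a1 and Rhd, of the red cell membrane, were at least 32.4-fold and 17.0-fold lower. Of 20 cell cycle genes 18 were lower, with a median log2 of -2.33 at percentile 0, including the mitotic genes Ccnb2 (at least 19.97-fold lower), Nusap1 (at least 23.2-fold lower) and Cenpf (39.2-fold lower with 3 UMIs, 13.2 to 192). Without the 14 erythroid-like cells the cell cycle median was -0.51, and the log2 folds of Hbb-bt and Hba-a1 turned to 2.51 and 3.098. Slc4a1, Nusap1, Ccnb2 and Rhd then had 0 EYFP positive UMIs against 2, 1, 5 and 0, and Cenpf 2 against 0, too few for a direction. Over every barcode, Hbb-bt and Hba-a1 stood at -0.78 and -1.55, and Nusap1 at -2.89.

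T-like cells of both libraries had similar levels of most preset lists, and differed in acinar and pancreatitis transcripts. Of the EYFP positive T-like cells 144 lay in a low-UMI cluster with no EYFP negative cell and 56 in another cluster, while 295 and 61 of the 389 EYFP negative ones lay in 2 further clusters. All 26 measured acinar secretory genes (median log2 6.49, or 6.45 at their bound, percentile 100) and all 6 pancreatitis genes (5.88, percentile 100) were higher in the EYFP positive library. Without the low-UMI cluster of 1 library these medians were 4.37 and 3.76. Tff2, a secreted mucosal peptide, had 62 UMIs against 2, and Lars2 was 31.4-fold higher (28.7 to 34.4). Nupr1 (40.2, 14.3 to 156), Spp1 (11.3, 5.23 to 26.6) and Apoe (7.99, 3.85 to 17.3) followed. Without that cluster Tff2 had 9 UMIs against 2 (log2 fold 4.71). Log2 folds were then 3.98 for Lars2, 3.54 for Nupr1 and 1.22 for Spp1. That of Apoe turned to -0.16 with 2 UMIs against 13. The EYFP positive UMIs lay thinly over cells, with the 62 of Tff2 in 52 cells and at most 3 in any cell. The 34 of Nupr1 lay in 26 cells, the 24 of Spp1 in 23 and the 22 of Apoe in 17. Whether Tff2, Nupr1, Spp1 and Apoe are the T-like cells' own RNA was not tested. The slopes on free RNA given below did not include them. Smaller differences were seen in Ccdc28a (2.98, 1.80 to 4.84), Cog4 (2.97, 1.66 to 5.21), Card6 (2.56, 1.74 to 3.72), Smg6 (2.27, 1.68 to 3.03) and Macf1 (1.93, 1.70 to 2.18), a cytoskeletal crosslinker. In cells thinned to 500 UMIs, Ccdc28a and Cog4 held 2 against 2 UMIs each and the log2 fold of Macf1 was 0.36, and as a mean over cells that of Ccdc28a was 0.66. Lower in the EYFP positive library were Nme2 by 3.50-fold (2.67 to 4.67) and Gstp1 by 3.45-fold (2.14 to 5.90). The chemokine Xcl1 had 1 UMI against 63. It had 9 against 63 (log2 -0.21) with at least 500 genes and at most 10% mitochondrial UMIs per barcode, where the class held other cells too. Xcl1 was also among the leading genes of the unnamed cluster of 31 EYFP positive cells. Its T-like fold therefore depends on which cells the rule named. Sostdc1 was at least 4.02-fold lower, with its 57 EYFP negative UMIs in 6 cells. Fam89b, Narf, Tiam1 and Chka had 1, 2, 3 and 4 EYFP positive UMIs and were 12.1-fold (2.08 to 485), 7.62-fold (2.03 to 64.1), 6.07-fold (2.01 to 30.0) and 5.24-fold (1.98 to 19.6) lower. The medians of the unfolded protein response (-0.14), immediate early (-0.02), interferon (0.09), cell cycle (-0.15) and DNA mismatch repair lists (0.21) lay between percentiles 25.7 and 90.0, and that of the MHC class II list (0.18, or 0.30 at its bound) at 94.6. Without the low-UMI cluster the MHC class II median was -0.22 and the cell cycle median -0.01, and the interferon median was -0.01 (-0.00902) with acinar, mitochondrial and ribosomal genes left out of the total. The median log2 fold of all genes in T-like cells was -0.10, and -0.21 under that total.

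B-like cells of the EYFP positive library had lower antigen presentation transcripts. All 8 measured genes of the list of MHC class II and apCAF genes were lower, with a median log2 of -0.45 at percentile 0.08, including Cd74 (0.737, 0.708 to 0.767), H2-Aa (0.711, 0.662 to 0.763), H2-Ab1 (0.820, 0.761 to 0.882) and H2-Eb1 (0.857, 0.797 to 0.922). Of 13 unfolded protein response genes 8 were lower (median -0.36, -0.65 to 0.09 over members, percentile 0.63), with Calr at 0.692 (0.536 to 0.886) but Hsp90b1 at 1.28 (1.05 to 1.56). In the EYFP negative library 1 cell with 44602 UMIs, which held 3273 of 4946 UMIs of the plasma cell gene Jchain, held 84 of 285 Hsp90b1 UMIs, and without it Hsp90b1 stood at 1.70. The list median was not computed without such cells, so whether it is lower in the other B-like cells is open. Egr1 was 5.99-fold lower (2.44 to 19.0), followed by Hist1h2ap (5.81-fold, 1.85 to 29.4), Ahctf1 (4.20-fold, 1.68 to 13.5) and Atp5k (2.48-fold, 1.66 to 3.82). For Egr1, 1 cell held 22 of the 67 EYFP negative UMIs. Its log2 fold was -2.58 with that cell, -2.08 without it and -2.75 without the top cell of each library. As a mean over cells it was -1.75. The sizes depend on the setting. With at least 500 genes and at most 10% mitochondrial UMIs per barcode, Hist1h2ap held 3 UMIs against 262 (log2 -4.63). The B-like class then held 112 EYFP negative cells, against 106 under the main filter. Other cells had thus entered the class, and this value is not a stronger difference in the same cells. Thinned to 500 UMIs, Atp5k held 2 against 13 (log2 -2.75), and Hist1h2ap and Ahctf1 0 against 4 each (bound of -0.47). The cell cycle, immediate early and interferon medians were -0.34, -0.19 and -0.19, at percentiles 6.09, 6.08 and 30.8. Macf1 (2.16, 1.77 to 2.64), Prpf4b (2.90, 2.16 to 3.89), Spp1 (33.6, 8.52 to 290) and Lars2 (39.3, 31.9 to 48.8) were higher, as were all 23 measured acinar secretory genes (median 6.29, or 5.98 with genes at 0 UMIs at their bound) and all 4 pancreatitis genes (6.43, or 4.34 at their bound). Without the cluster of 1 library the acinar secretory median was 5.08 and the log2 fold of Spp1 2.47, with 4 UMIs against 2. Cep350 (2.61, 1.63 to 4.20) and Ddx27 (2.99, 1.64 to 5.53) were higher as sums, but cells thinned to 500 UMIs held 4 against 3 UMIs of Cep350 (log2 0.36) and 2 against 2 of Ddx27. Itgb1 was 3.64-fold higher (1.88 to 7.26), and 1.03-fold without 1 cell. Several immunoglobulin genes were set by single cells. In the EYFP negative library 1 cell held 6821 of 6829 Ighg2b UMIs and another held all 200 UMIs of Ighv3-6, all 184 of Igkv12-46 and 9293 of 11394 of Ighm. Ighm was 1.999-fold lower in the EYFP positive library with that cell and 2.54-fold higher without it, but 1 EYFP positive cell held 1722 of the 2546 UMIs there. Without both cells 824 UMIs stood against 2101, a log2 fold of -0.18. In the EYFP positive library 1 cell held all 81 UMIs of Ighv11-2 and all 70 of Igkv14-126, and another all 99 of S100a6, against 47 in the EYFP negative library, of which 34 lay in 1 cell. Of the 110 EYFP positive B-like cells 63 lay in a low-UMI cluster without EYFP negative cells. Without that cluster the MHC class II median was -0.45 as well, and the interferon median 0.09.

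**Figure D3:**
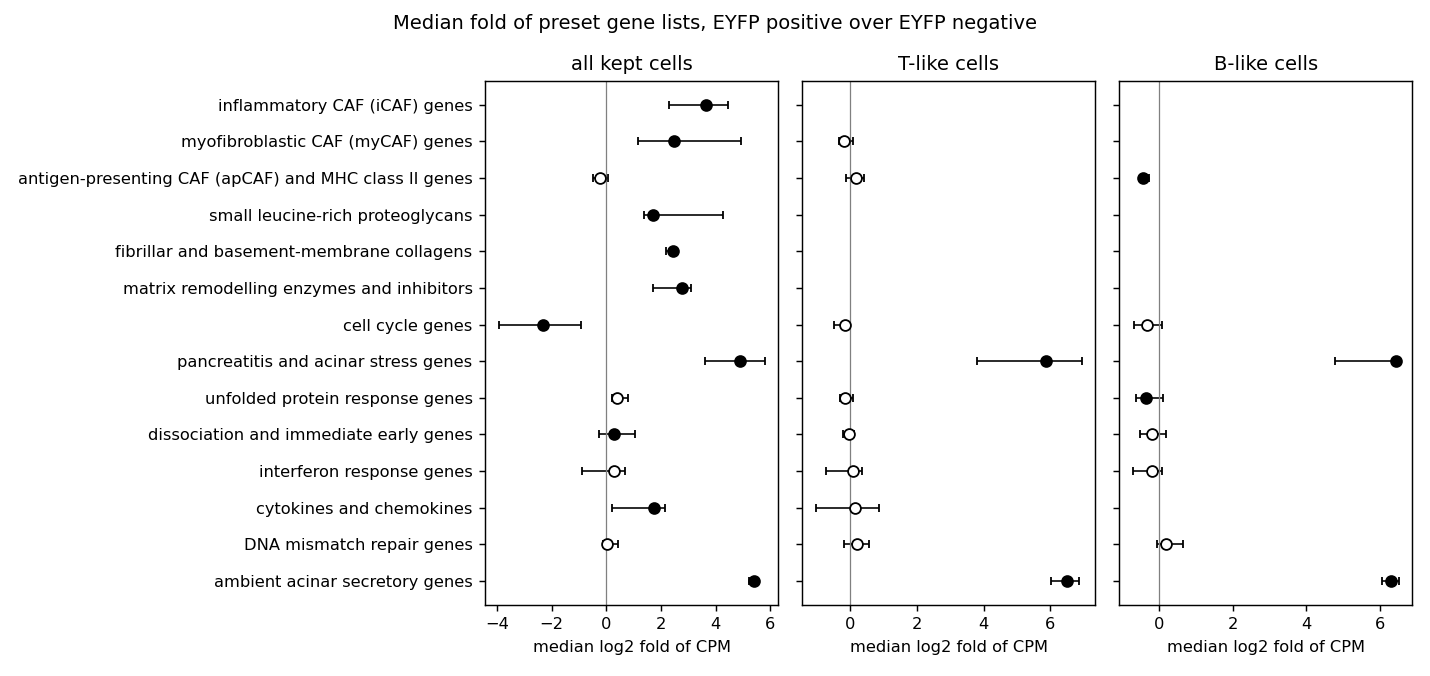
Median log2 fold of CPM, EYFP positive over EYFP negative, of each preset gene list in all kept cells, T-like cells and B-like cells. Whiskers are 95% bootstrap intervals over list members, and filled points lie outside the central 95% of matched random lists. Acinar secretory genes lie at 5.41, 6.49 and 6.29 in the 3 panels.

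DNA mismatch repair genes, which act on repeat slippage errors, went both ways over all kept cells. Of 8 genes 4 were higher and 4 lower (median log2 0.01, percentile 22.2, or -0.21 with acinar, mitochondrial and ribosomal genes left out of the total), with Msh3 at 0.990 (0.755 to 1.29) and Mlh3 at 1.30 (0.921 to 1.81). In T-like cells 5 of 7 were higher (0.21, percentile 87.5), with Msh3 at 1.68 (1.15 to 2.42), and in B-like cells 5 of 7 (0.19, percentile 93.4).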

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

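The barcodes left out by the filter on genes and mitochondrial share hold a signal outside the comparisons. Hemoglobin genes made up 74.9% of the 438606 UMIs in the 192 EYFP negative barcodes left out, and 9.18% of the 1261465 UMIs in the 857 EYFP positive ones. The EYFP positive barcodes left out held 40.7% mitochondrial UMIs, against 14.7% in the other library. No biological explanation was tested for this difference.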

How the results depend on the processing

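Alternatives on naming rules, on cells with at least 1000 or 5000 UMIs, on clusters of 1 library, on erythroid-like cells and on single cells were chosen after seeing the data. For differences in class shares, 55 alternative values stayed within the counting interval of the difference, 28 moved out of it and 1 turned. For gene folds 333 stayed within it, 94 moved out and 8 turned, while 45 gave no fold because both libraries held at most 3 UMIs or the bound against 3 UMIs left the direction open, and for list medians 158 stayed within the spread of their members and 12 moved out. Causes were not tested unless given.

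The share differences in percentage points (EYFP positive minus negative) moved as follows. With every barcode: T-like -37.0, acinar-like 21.0, ductal-like 14.8, fibroblast-like 3.097. At Leiden resolution 0.5: ductal-like 29.4. At resolution 2.0: T-like -50.9, acinar-like 18.7, ductal-like 18.9. With each library clustered by itself: T-like 22.6, acinar-like 14.8, endothelial-like 1.14, ductal-like 16.2, fibroblast-like 2.92. There the T-like sign turned, with 0 EYFP negative cells named T-like. The median cluster of a mostly T-like library can itself be T-like, so this turn says nothing on the T-like share. With a class per cell from marker UMIs: B-like -13.3, T-like -60.0, acinar-like 60.2, endothelial-like 1.33, ductal-like 8.13, fibroblast-like 2.22. With names from summed CPM against all other cells: T-like -61.8, acinar-like 27.0, endothelial-like 1.05, ductal-like 2.89, macrophage-like 4.17. With names from summed CPM against the median cluster: endothelial-like 1.05 and ductal-like 2.89. Among cells with at least 1000 UMIs: acinar-like 17.6 and ductal-like 17.6. Under the strict filter: macrophage-like 5.19. No cell was macrophage-like at resolution 0.5 or with each library clustered by itself. These empty differences are counted among the values that stayed, though they say nothing on stability. With ties named, none of the 7 differences left its counting interval.

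Ogn in fibroblast-like EYFP positive cells was 1406 CPM thinned to 500 UMIs, 1130 thinned to 1000, 1449 as a mean over cells, 1716 without the cell with the most UMIs and 2318 in cells with at least 5000 UMIs. In EYFP negative cells it was 0 CPM thinned to 500 UMIs (6 cells) and 200 CPM thinned to 1000 (5 cells), where 1 UMI decides. The 12 list medians that moved were as follows. Without erythroid-like cells: cell cycle -0.51. Under the other total: acinar secretory 5.199, unfolded protein response 0.18 and mismatch repair -0.21 in whole libraries, MHC class II -0.50 in B-like cells. Without clusters of 1 library: acinar secretory 5.08 and interferon 0.09 in B-like cells, acinar secretory 4.37, pancreatitis 3.76, MHC class II -0.22 and cell cycle -0.01 in T-like cells. From 1 UMI: pancreatitis 1.65 in fibroblast-like cells.

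Without the cell with the most UMIs the log2 folds in B-like cells turned to 1.35 for Ighm and to a bound of -2.73 for S100a6 (0 UMIs against 47). Without Scrublet doublets Ighm stood at 1.28. In both settings 1722 of the 2546 EYFP positive Ighm UMIs lay in 1 cell, and without the top cell of each library Ighm stood at -0.18 and S100a6 at a bound of -0.91 (0 UMIs against 13). As means over cells 30 gene folds moved and 31 stayed, and thinned to 500 UMIs 11 moved and 12 stayed. Without erythroid-like cells Hbb-bt stood at 2.51 and Hba-a1 at 3.098. Apoe in T-like cells, with 2 UMIs against 13, stood at -0.11 under the strict filter and -0.16 without clusters of 1 library. No paired analysis was possible because each group is 1 library. Depth limits every EYFP positive class, where a gene at 0 in 6 EYFP negative fibroblast-like cells or in a class of low UMIs is not shown to be absent.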

Other observations

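The tests of both slopes on UMIs, of low-UMI barcodes by share and of tissue preparation or sort were chosen after the result was seen. The genes in this paragraph were also chosen after their values were seen. T-like cells of the EYFP positive and negative libraries held similar levels of subset genes: Cd4 at 86.3 and 92.2 CPM, Cd8a at 179 and 201 CPM and Tcf7 at 360.3 and 359.9 CPM. Foxp3 stood at a fold of 0.773 (0.336 to 1.58). Ly6a (0.536, 0.4004 to 0.706) and Ccr7 (0.701, 0.567 to 0.860) were lower in the EYFP positive library. S100a4 stood at 0.692 (0.541 to 0.875), but 1 EYFP negative cell held 86 of 553 UMIs, and without it the fold was 0.817. That value keeps 1 EYFP positive cell that held 30 of the 81 UMIs there, so it does not show a weaker difference. In fibroblast-like cells, against 0 to 5 UMIs per gene in the 6 EYFP negative cells, Pi16 was 61.5-fold higher (16.9 to 510), Sema3c 54.5-fold (9.67 to 2165), Cd248 24.8-fold (6.77 to 207) and Igfbp6 17.5-fold (7.40 to 54.2), and Dpp4, with 76 UMIs against 0, at least 7.23-fold. Pi16 is also a naming marker. Mgp (fold 0.174, 0.137 to 0.221) and Gdf10 (0.0692, 0.0276 to 0.153) were lower, but 1 EYFP negative cell held 91 of its library's 190 Mgp UMIs and another 19 of the 33 Gdf10 UMIs. Without the respective EYFP negative cell the folds were 0.263 and 0.129. These values keep the EYFP positive cells that held 45 of 116 Mgp UMIs and 3 of 8 Gdf10 UMIs there, so they do not show weaker differences.

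Acinar secretory genes and Lars2 were higher in T-like and B-like cells of the EYFP positive library. If the UMIs were free RNA, their number per droplet would not grow with the cell's own UMIs. Over 338 EYFP positive T-like and B-like cells the log2 slope on other UMIs was -0.304 for acinar secretory genes and 0.0939 for Lars2 with Gm42418, against 0.601 for mitochondrial genes, which cells make themselves, while in the EYFP negative library the slope was 0.494 for Lars2 with Gm42418, so part of these UMIs may be the cells' own. The mitochondrial slope itself stayed under the limit used for a cell's own RNA, so the slopes separate free from own RNA only in part. The 38 acinar genes also stood in like ratio in T-like and fibroblast-like cells (Spearman correlation 0.984 across genes, which are not independent replicates). Between T-like and acinar-like cells the correlation was 0.978. Any RNA from acinar cells, free or taken up, would give this order, so it does not tell these sources apart. Free RNA is a candidate explanation for these folds, while uptake of acinar material by the cells was not tested.

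In summed UMIs, long genes such as Macf1 stood higher than short genes in T-like and B-like cells. Across genes with at least 100 UMIs, log2 fold correlated with transcript length at a Spearman value of 0.198 in 4233 genes of T-like cells and 0.309 in 1090 genes of B-like cells. The limit set beforehand was 0.2 in both classes, so a length trend of the library stays open, and so does the kit, which sets the transcript end that is read. Without the low-UMI clusters of the EYFP positive library the T-like correlation was 0.203, so the trend in sums does not need them. That outcome was nearly fixed by the sums, since 66 cells with at least 5000 UMIs held 532713 of the 718832 EYFP positive T-like UMIs. It therefore says little about low-UMI cells themselves. As a mean over cells, where low-UMI cells weigh more, the correlation was 0.0703 in T-like cells and 0.259 in B-like cells. In cells thinned to 500 UMIs it was 0.0745 and 0.170. A biological difference between the sorted fractions stays untested.

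The lower T-like share of the EYFP positive library could come from its many low-UMI barcodes. Among cells with at least 1000 UMIs the difference was still -42.2 percentage points, which argues against that as the whole cause. The size does depend on the names, with -61.8 points from summed CPM against all other cells. Where each library was clustered by itself the sign turned, but the rule then named 0 EYFP negative cells T-like. It asks for markers above the median cluster of the same library, which can itself be T-like where most cells are. That turn is therefore no evidence on the T-like share. Tissue preparation, the sort and the EYFP state cannot be told apart, since each group has 1 library.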
